A study of Mus musculus with 20 samples.

How the data were processed

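Gene expression was measured in 6 polyA RNA libraries from microdissected mouse brain tissue, and the 14 bisulfite samples of the series were not analysed here. The deposited values are raw read counts per gene symbol, 1 table per library, with 34620 symbols and 5 summary lines of the HTSeq counter. The submitters' processing notes name Bismark, TopHat2 2.0.2, TopHat, Bowtie 1.0.0, methylKit, HTSeq and edgeR, and the builds mm9 and NCBIM37, without saying which served which data. No strand setting is stated. Of the symbols, 29294 matched a current symbol in the reference table of another build (GRCm38.p6), and no coordinates are given.

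Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Libraries were scaled by TMM, genes with low counts were removed with filterByExpr, and 19192 genes were tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. CPM values in the text are TMM-scaled, with factors of 1.11 in HP, 1.11 in SP, 1.10 in yCA, 1.18 in yMSN, 0.790 in dMSN 1 and 0.795 in dMSN 2. The SE of a log2 change was its size divided by the square root of F. Young against precursor and striatal against hippocampal were contrasts of a model with lineage and stage over all 6 libraries, with 2 residual degrees of freedom. The comparison of dMSN with yMSN used 1 mean per cell group, with 1 residual degree of freedom. Pairs of single libraries have no test, and their log2 ratios use a prior count of 2 with an exact 95% interval that covers counting error only. Intervals and floors (3 counts for a count of 0) cover counting error only.

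Gene lists numbered 23 and were fixed before the data were examined, as were the comparisons, the tests, the alternatives in the closing section not said to be added, and the rule for named genes. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. With the preset correlation 16, 5 and 17 lists passed in the 3 comparisons, and with the estimated correlation none did. The estimated version takes its degrees of freedom from the fit, 2 or 1, so hardly any list could pass and a failure decides nothing. In dMSN against yMSN the medium spiny neuron signalling list, with an estimate of -0.043, went from adjusted p = 2.4e-10 to 0.406. The preset version may be too lenient, since the cell cycle estimate was 0.41 in young against precursor. For single pairs a list median was set against 10000 random lists, drawn with replacement within bins of mean expression. Another 10 lists, of tissues that the libraries were seen or suspected to hold, were written after the data had been seen and are described as levels.

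The named genes are the 12 largest increases and 12 largest decreases per comparison among genes past the threshold with a mean of at least 5 CPM and the same direction in both matched pairs, ranked by the smaller of the 2 log2 ratios. Predicted, clone-named and pseudogene symbols were skipped, and a few genes that the rule names are not reported here. Where fewer than 12 passed, the ranking was continued and the genes are said not to pass. Up to 4 members per list with at least 1 CPM were named by the size of their change, and the methylation, sex-linked and other cell type lists could be named in full. For single pairs the 6 largest in each direction with at least 5 CPM were eligible. Acta1, Omp and Krt15 were chosen after their values were seen.

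Alternatives in edgeR were relative log expression (RLE) scaling, upper quartile scaling, no filter, a filter at 1 CPM in 2 libraries, robust moderation and the other model. Further alternatives were DESeq2 1.42.0, limma voom, subsets of libraries and each library left out in turn. The steps were tested on simulated counts with 200 changed genes among 19192. At 2-fold, 62.0% of the changed genes were recovered for young against precursor, 64.0% for striatal against hippocampal and 43.0% for dMSN against yMSN. At 4-fold the shares were 82.5%, 80.5% and 81.0%. The simulated spread came from the dMSN pair and says nothing of spread between lineages. The counting interval covered 96.6% of simulated ratios. Per library, 5.34% to 9.81% of reads fell in no gene, 1.38% to 2.01% were ambiguous and 17.3% to 27.3% aligned to several places.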

Results

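The series holds 20 mouse brain samples, 14 measured by enhanced reduced representation bisulfite sequencing and 6 by polyA RNA sequencing. The RNA libraries carry gene counts and are described here, and the 14 bisulfite samples were not analysed here. The 6 RNA libraries came from microdissected tissue that the labels give as male C57BL/6 wild type. They comprise 1 library of hippocampal precursors (HP), 1 of striatal precursors (SP), 1 of young hippocampal CA pyramidal neurons (yCA), 1 of young medium spiny neurons (yMSN) and 2 of dorsal medium spiny neurons (dMSN), which the labels write as medial spiny neurons. HP, SP, yCA and yMSN have no replicates, so errors on levels are given for dMSN alone, as an SD over its 2 libraries. The counts assigned to genes were 31282185 in HP, 35874646 in SP, 35418531 in yCA, 36969136 in yMSN, 152347673 in dMSN 1 and 145713678 in dMSN 2. A count of 0 allows up to 0.0861 CPM (read counts scaled to library size) in HP and up to 0.0249 CPM in dMSN 1, counting error only.

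Libraries of the same stage were the most alike. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.986 between HP and SP, 0.959 between yCA and yMSN, and 0.991 between dMSN 1 and dMSN 2. The dMSN libraries correlated with HP at 0.713 and 0.721. The first principal component held 72.4% of the variance and ran from the precursor libraries through the young ones to dMSN.

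Some transcripts that are not typical of brain were abundant in the young libraries. A list of 25 skeletal muscle genes, written after the data had been seen, had a median of 215 CPM in yCA and 67.4 CPM in yMSN, against 0.890 CPM in HP, 0.780 CPM in SP, 1.21 CPM in dMSN 1 and 0.837 CPM in dMSN 2. Acta1, skeletal muscle actin, stood at 1460 CPM in yCA and 500.1 CPM in yMSN. A list of 20 bone and cartilage genes had a median of 28.5 CPM in yMSN and 1.52 CPM in yCA. The 14 genes of the olfactory epithelium list had a median of 35.4 CPM in yMSN and 0.244 CPM in yCA, and Omp, the olfactory marker protein, stood at 42.9 CPM in yMSN. The epidermis and oral epithelium list had a median of 6.86 CPM in yCA and 13.9 CPM in yMSN, and below 1 CPM in the other libraries. Tg, the thyroid hormone precursor, stood at 76.6 CPM in yCA and 0.967 CPM in yMSN. These levels accompany every young library value given below.

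**Figure D1:**
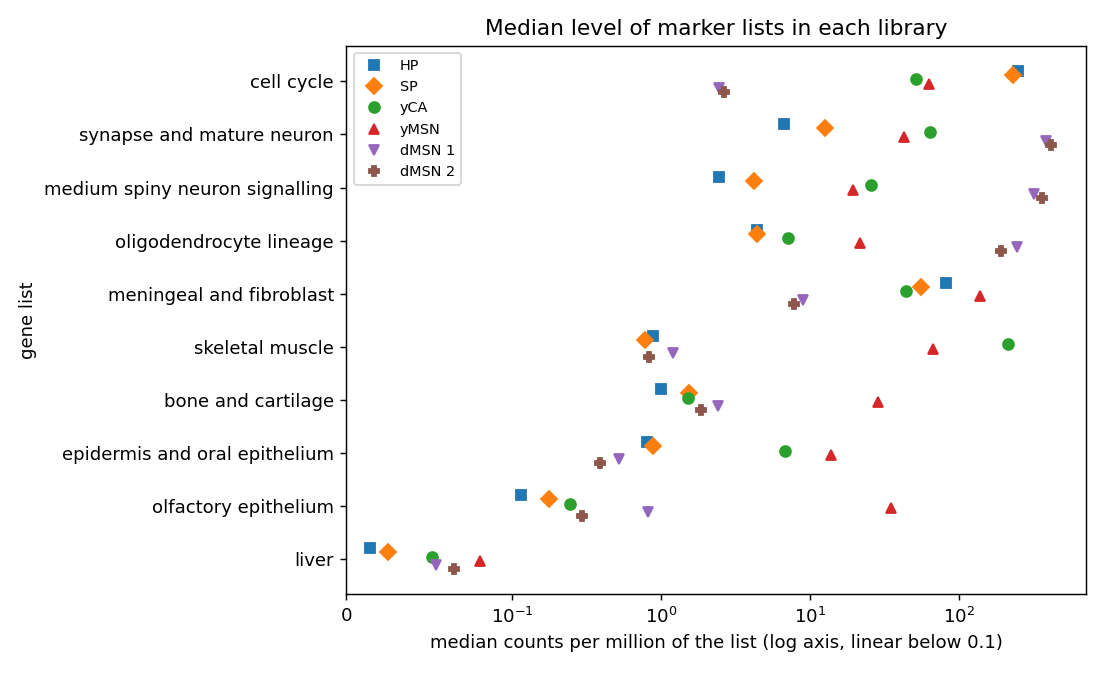
Median CPM of 10 gene lists (vertical axis) in each of the 6 libraries (horizontal axis, log scale, linear below 0.1), 1 point per library. The skeletal muscle list lies at 215 CPM in yCA and 67.4 CPM in yMSN, and the synapse list is highest in dMSN, at 385 and 419.7 CPM.

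Sex-linked transcripts differed between libraries that are all labelled male. Xist, the RNA that silences an X chromosome in female cells, stood at 857 CPM in HP, 1088 CPM in SP, 762 CPM in yCA and 489 CPM in yMSN, with 4 counts in dMSN 1 and 0 in dMSN 2. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d together had 672 counts in HP, 0 in SP, 0 in yCA, 2108 in yMSN, 8258 in dMSN 1 and 9348 in dMSN 2. For young against precursor, 0 of 6 sex-linked genes tested passed (adjusted p = 0.497 for the list, and adjusted p = 0.758 with an estimated correlation).

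The first comparison asked which transcripts differ between young tissue and precursors in both lineages. Of 19192 genes tested, 4169 were higher and 2629 lower in young tissue. Of these 6798 genes 6777 went the same way in both lineages, which the model favours, since a difference between the lineages' changes counts as spread. All 30 cell cycle genes fell, and 25 of 29 synapse genes and 19 of 23 medium spiny neuron signalling genes rose. As groups, these 3 lists each had adjusted p = 0.328 with an estimated correlation, a version with 2 degrees of freedom that hardly any list could pass. Across genes, the change from HP to yCA correlated with the change from SP to yMSN at r = 0.726 (Spearman 0.723). At least 2-fold changes went the same way in both lineages for 4814 genes and opposite ways for 273.

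All 30 cell cycle genes fell, and all 30 did so adjusted over the list alone, with a median log2 change of -1.94. Bub1, a spindle checkpoint kinase, fell by 2.53 on the log2 scale (SE 0.213, adjusted p = 0.0022), and Rrm2, a subunit of ribonucleotide reductase, fell by 2.45. For the list, camera gave adjusted p = 3.6e-31 at the preset correlation and adjusted p = 0.328 with an estimated correlation. Of 15 radial glia and neural stem cell genes, 10 fell and 3 rose (11 and 4 adjusted over the list alone). Sox3 fell by 2.78 and Hes5, a Notch target, fell by 2.33 on the log2 scale, while Tnc, an extracellular matrix protein, rose by 4.28. That list had adjusted p = 0.022 at the preset correlation and adjusted p = 0.328 with an estimated correlation. Of 12 neurogenic progenitor genes 6 fell and 2 rose (7 and 2 adjusted over the list alone), with adjusted p = 0.044 at the preset correlation and adjusted p = 0.513 with an estimated correlation. Eomes, a marker of intermediate progenitors, was among those that rose.

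Of 29 synapse and mature neuron genes, 25 rose and 1 fell, the same counts adjusted over the list alone. Camk2b, a calcium-dependent kinase of synapses, rose by 6.06 on the log2 scale (SE 0.373, adjusted p = 0.0014), and the glutamate receptor genes Grin2b and Gria2 rose by 5.86 and 5.08. For these genes camera gave adjusted p = 1.0e-18 at the preset correlation and adjusted p = 0.328 with an estimated correlation. Of 23 medium spiny neuron signalling genes, 19 rose (22 adjusted over the list alone). The median log2 ratio of the list was 3.25 for yCA over HP and 2.12 for yMSN over SP. It was 0.61 for SP over HP and -0.51 for yMSN over yCA, where 19 of 23 members were lower in yMSN. Ppp1r1b, which encodes DARPP-32, rose by 5.52. The list had adjusted p = 1.7e-15 at the preset correlation and adjusted p = 0.328 with an estimated correlation. Of 17 immature neuron genes, 13 rose (14 adjusted over the list alone), among them Dcx, a microtubule protein of migrating neurons, which rose by 2.69. That list had adjusted p = 5.0e-04 at the preset correlation and adjusted p = 0.513 with an estimated correlation. Of 21 pallial glutamatergic identity genes, 10 rose and 4 fell, the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.079, and adjusted p = 0.401 with an estimated correlation). Its transcription factors Neurod6 and Neurod2 rose by 8.70 and 8.02, while Wnt8b fell by 4.52. Of 23 subpallial GABAergic and striatal transcription factor genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone), with adjusted p = 0.0027 at the preset correlation and adjusted p = 0.328 with an estimated correlation. Gad1, an enzyme of GABA synthesis, rose by 4.03.

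Of 25 DNA methylation machinery genes, 8 fell and 3 rose, the same counts adjusted over the list alone. Dnmt1, the maintenance methyltransferase, fell by 1.10 on the log2 scale (SE 0.150, adjusted p = 0.0060), and its partner Uhrf1 fell by 2.53. The de novo methyltransferase Dnmt3b fell by 2.56 and the chromatin remodeller Hells fell by 2.61. Dnmt3a did not pass the test (log2 change -0.33, SE 0.169, adjusted p = 0.189), nor did the methylcytosine dioxygenases Tet1, Tet2 and Tet3, at log2 changes of 0.08, 0.18 and -0.06. The sign of the Tet1 value changed with RLE scaling, and the signs of Tet1, Tet2 and Tet3 changed when single libraries were left out. Zbtb4, a protein that binds methylated DNA, rose by 2.05. Apobec2, a deaminase known from skeletal muscle, rose by 5.92 and stood at 47.4 CPM in yCA and 20.1 CPM in yMSN, where the muscle genes described above were high. The list had adjusted p = 0.044 at the preset correlation and adjusted p = 0.328 with an estimated correlation.

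**Figure D2:**
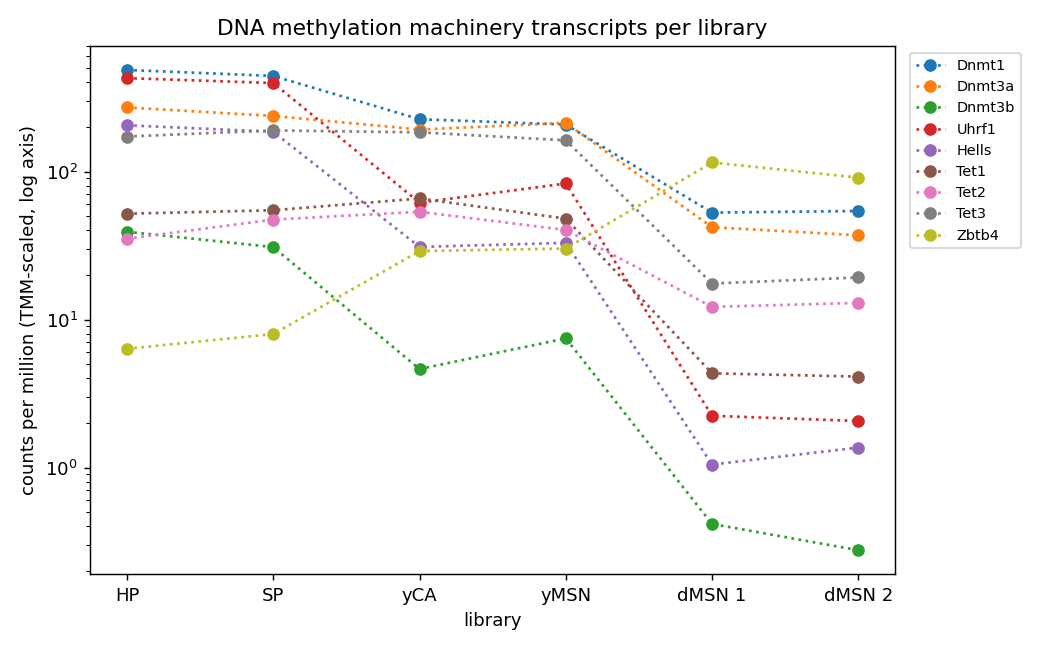
CPM (log axis) of 9 genes of the DNA methylation machinery list in each of the 6 libraries, 1 point per library. Dotted lines join the points of a gene and are no time course. Dnmt3a lies at 271 CPM in HP, 213 CPM in yMSN, and 42.0 and 37.1 CPM in the dMSN libraries.

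The genes with the largest increases were mostly genes known from tissues outside the brain. Krt13, Krt6a and Krt4, keratins of stratified epithelia, were at or below 0.101 CPM in both precursor libraries. Krt13 stood at 56.8 CPM in yCA and 66.2 CPM in yMSN. Ckm, Casq2, Myl1, Myl4, Cox6a2 and Tmem8c, genes of striated muscle, were also among the 12, with Ckm at 391 CPM in yCA and 103 CPM in yMSN. Aspn, of the extracellular matrix, and Ptgds, a prostaglandin synthase, were also in the group. Ptgds and Myl4 were also abundant in dMSN, at 1360 ± 165 CPM and 62.0 ± 16.9 CPM (SD, n = 2). Cox6a2 stood at 22.7 ± 7.40 CPM in dMSN (SD, n = 2), against 25.3 CPM in yCA and 9.44 CPM in yMSN. The embryonic globins Hbb-bh1, Hbb-y and Hba-x had the largest decreases. Hbb-bh1 stood at 396 CPM in HP and 423 CPM in SP, and fell by 9.79 on the log2 scale (SE 0.239, adjusted p = 0.0010). Lin28a, an RNA-binding protein of early embryonic cells, fell by 7.13, and Trim71, Sall4, En2, Nkx6-1, Greb1, Dusp9, Igdcc3 and Hemgn fell by 4.97 to 6.89. En2, a gene of midbrain and hindbrain, stood at 98.8 CPM in SP and 17.8 CPM in HP. The midbrain, hindbrain and spinal cord list, written after the data had been seen, had a median log2 ratio of -4.99 for yMSN over SP, where 17 of 18 members were lower, and -1.58 for yCA over HP, where 12 were lower.

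The tests were made in edgeR with lineage and stage as terms and 2 residual degrees of freedom. The count was 3590 without dMSN 1, 3646 without dMSN 2 and 4421 without either; each leaves 1 residual degree of freedom. The share of called genes that rose was 61.3%, and 52.4% with RLE scaling, which moved the median log2 change of all genes from 0.10 to -0.02.

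The second comparison asked which transcripts differ between the striatal and the hippocampal lineage at both stages. In edgeR, 0 of 19192 genes passed, with 826 at an unadjusted p below 0.05. DESeq2 called 60 genes and limma voom 0. Across genes, the difference of SP from HP correlated with that of yMSN from yCA at r = -0.158 (Spearman -0.216). The values below are described although none passed.

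Among the genes that were lower in the striatal libraries at both stages were transcription factors and signals of the developing pallium. Wnt8b, a signal of the cortical hem, stood at 61.0 CPM in HP and 20.4 CPM in SP, and at 2.80 CPM in yCA and 0.829 CPM in yMSN (log2 difference -1.66, SE 0.285, adjusted p = 0.896). Fezf2 and Emx1, transcription factors of the forebrain, each had a log2 difference of -1.32. Trdn, Myoz1, Myog, Cox6a2, Alpk3 and Adssl1, known from muscle, also had lower values, as did AW047730. In HP, Trdn, Myoz1 and Cox6a2 stood at 0.0574, 0.201 and 0.0287 CPM, and in SP at 0, 0.0504 and 0 CPM. These values lie at or near the counting floor, so for these genes the precursor pair says little. Their differences rest on the young pair, where the skeletal muscle list was higher in yCA. Dynlrb2, Ccdc108, Dnahc6, Wdr52 and Ccdc67, mostly genes of cilia or centrioles, had higher values in the striatal libraries, as did Cnpy1, Acan, En1, Pcp4l1, Cyp2a5, Cyp2f2 and Stk32a. Acan, the cartilage proteoglycan aggrecan, stood at 41.0 CPM in yMSN, where the bone and cartilage list was high. Cyp2a5 stood at 0 CPM in HP and 0.0504 CPM in SP, near the floor, and its difference rests on yMSN, at 33.1 CPM. Cyp2f2 was also near the floor in the precursors, at 0.0287 CPM in HP and 0.126 CPM in SP. In HP, Dnahc6 and Dynlrb2 stood at 0.0861 and 0.144 CPM, at or near the floor. En1 belongs to the midbrain, hindbrain and spinal cord list, and stood at 17.3 CPM in SP and 4.19 CPM in HP.

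Of 21 pallial glutamatergic identity genes, 0 passed over all genes tested and 1 was lower adjusted over the list alone, with a median log2 difference of -0.56. For the pallial list camera gave adjusted p = 1.1e-11 at the preset correlation and adjusted p = 0.469 with an estimated correlation. Its median was -0.42 between SP and HP, where 12 members were lower and 9 higher, and -0.98 between yMSN and yCA, where 19 were lower and 2 higher. Lower values in yMSN than in yCA were not particular to this list. The synapse, immature neuron and hippocampal neuron lists had medians of -0.45, -0.61 and -0.55 there, with 28 of 29, 17 of 17 and 15 of 18 members lower. Between SP and HP their medians were 0.36, 0.69 and 0.29. The subpallial GABAergic and striatal transcription factor list had a median log2 difference of 0.04 (adjusted p = 0.587, and adjusted p = 0.823 with an estimated correlation). In the contrast over both stages, 4 lists were higher in the striatal lineage at the preset correlation. They were microglia, meninges and fibroblasts, choroid plexus and ependyma, and erythroid cells, with adjusted p = 1.5e-06, 3.1e-04, 3.1e-04 and 0.038. The meningeal and fibroblast list was not higher at both stages. Its median was -0.23 in SP minus HP, with 4 higher and 6 lower, and 2.20 in yMSN minus yCA, with all 10 higher. For the erythroid list these medians were 0.04 and 0.58. None of the 4 lists passed with an estimated correlation, where the lowest adjusted p = 0.581. With 2 degrees of freedom hardly any list could pass that version.

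**Figure D3:**
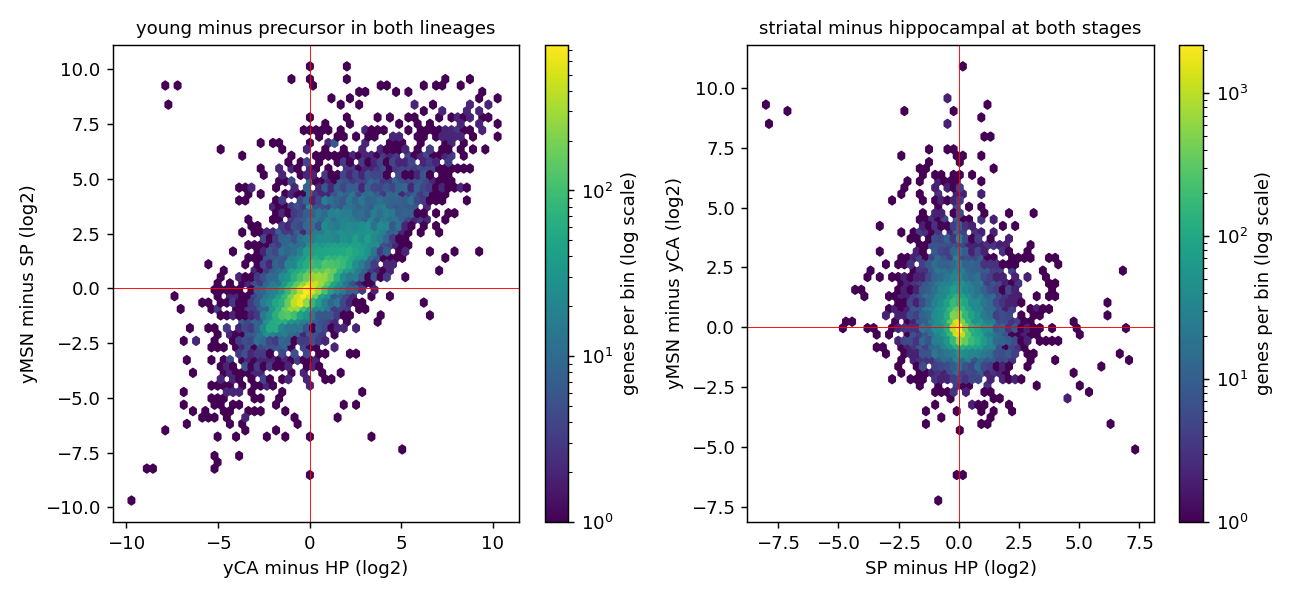
Log2 ratios of 19192 genes, counted in hexagonal bins (colour, log scale). Left, yMSN minus SP against yCA minus HP (r = 0.726). Right, yMSN minus yCA against SP minus HP (r = -0.158).

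The count of 0 depends on the libraries and the model. It was 356 with 1 mean per cell group, where the dMSN pair alone gives the spread. It was 1495 without HP, 1515 without SP, 116 without yCA and 130 without yMSN, but these fits compare the lineages at 1 stage only, 1 library against 1, with the spread again from the dMSN pair. In single pairs, which have no test, 339 of 11469 genes with at least 5 CPM in the higher library differed at least 2-fold between SP and HP, and 1372 of 12815 between yMSN and yCA. Atoh1, a hindbrain transcription factor, stood at 12.1 CPM in SP and 0.0574 CPM in HP, and Hoxa2, of the hindbrain, at 6.37 CPM in SP and 0.0574 CPM in HP. A list of 21 genes of midbrain, hindbrain and spinal cord, written after the data had been seen, had a median of 4.63 CPM in SP and 0.316 CPM in HP. The eye list, written at the same time, had a median of 1.72 CPM in HP and 0.680 CPM in SP, and Pmel, a pigment cell protein, stood at 13.2 CPM in HP and 1.74 CPM in SP.

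The third comparison asked which transcripts differ between dMSN and yMSN. Of 19192 genes, 6162 were higher and 6786 lower in dMSN. Most of the listed genes of medium spiny neuron signalling, synapses and glia rose, and most of those of the cell cycle, meninges and red cells fell. As groups, none of these lists passed with an estimated correlation, where adjusted p = 0.406 was the lowest. With 1 degree of freedom hardly any list could pass that version. The labels give dMSN no age.

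Of 23 medium spiny neuron signalling genes, 22 rose and 1 fell, the same counts adjusted over the list alone. Rasd2, a striatal small GTPase, rose by 7.47 on the log2 scale (SE 0.305, adjusted p = 2.4e-09), and Ppp1r1b rose by 7.05 to 2524 ± 72.2 CPM (SD, n = 2). The signalling list had adjusted p = 2.4e-10 at the preset correlation and adjusted p = 0.406 with an estimated correlation. Of 29 synapse and mature neuron genes, 26 rose (27 adjusted over the list alone), and Nrgn, a postsynaptic calmodulin-binding protein, rose by 9.07 to 5566 ± 734 CPM (SD, n = 2). That list had adjusted p = 1.0e-10 at the preset correlation and adjusted p = 0.406 with an estimated correlation. Of 10 interneuron and cholinergic genes 8 rose and 2 fell, with Pvalb and Cck, which mark interneurons, up by 9.92 and 8.69 (adjusted p = 0.0058 for the list, and adjusted p = 0.406 with an estimated correlation). Of 23 subpallial GABAergic and striatal transcription factor genes, 6 rose and 13 fell, with a median log2 change of -0.78, and the list did not pass (adjusted p = 0.287, and adjusted p = 0.604 with an estimated correlation). Of 18 hippocampal neuron marker genes, 11 rose and 4 fell (adjusted p = 0.040, and adjusted p = 0.477 with an estimated correlation). Of 21 pallial glutamatergic identity genes, 3 rose and 11 fell (adjusted p = 0.179, and adjusted p = 0.477 with an estimated correlation), and Slc17a7, a vesicular glutamate transporter of cortical neurons, rose by 5.18 to 1212 ± 389 CPM (SD, n = 2). Of 11 choroid plexus and ependyma genes, 5 rose and 4 fell, and the list did not pass (adjusted p = 0.287, and adjusted p = 0.604 with an estimated correlation). Its most abundant member, Ttr, stood at 5463 and 4293 CPM in the dMSN libraries.

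Of 16 oligodendrocyte lineage genes, 14 rose and 2 fell. Opalin, a myelin protein, had 0 counts in yMSN and was at least 1371-fold higher in dMSN, taking 3 counts as the floor. Mobp and Mag, also of myelin, rose by 11.36 and 9.21. The oligodendrocyte list had adjusted p = 5.8e-06 at the preset correlation and adjusted p = 0.477 with an estimated correlation. Of 13 astrocyte genes 11 rose, Gfap by 6.87, and of 14 microglia genes 13 rose, P2ry12 by 3.98. These lists had adjusted p = 3.6e-05 and 2.0e-05 at the preset correlation and adjusted p = 0.406 for both with an estimated correlation. Of 17 immediate early and stress genes, 14 rose and 1 fell, Egr4 by 8.49 and Arc by 6.56 (adjusted p = 3.2e-04 for the list, and adjusted p = 0.477 with an estimated correlation).

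Of 30 cell cycle genes, 28 fell (28 adjusted over the list alone), Bub1 by 7.78 and Top2a by 6.71, with adjusted p = 3.7e-12 for the list and adjusted p = 0.406 with an estimated correlation. All 10 meningeal and fibroblast genes fell, and Col1a1, a collagen chain, fell by 9.25. All 12 erythroid genes fell. These lists had adjusted p = 1.4e-05 and 5.3e-06, and adjusted p = 0.406 for both with an estimated correlation. Of 14 endothelial and pericyte genes, 11 fell and 2 rose (adjusted p = 0.0053, and adjusted p = 0.538 with an estimated correlation). Of 26 imprinted genes, 20 fell and 4 rose, and H19, a maternally expressed RNA, fell by 14.15 from 3671 CPM in yMSN. The imprinted list had adjusted p = 7.4e-05 and adjusted p = 0.406 with an estimated correlation.

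Of 25 DNA methylation machinery genes, 17 fell and 7 rose, the same counts adjusted over the list alone. Dnmt3a fell by 2.43 on the log2 scale (SE 0.196, adjusted p = 4.2e-07), from 213 CPM to 39.6 ± 3.50 CPM (SD, n = 2). Dnmt1 fell by 1.96 and Uhrf1 by 5.27. Tet1, Tet2 and Tet3 fell by 3.51, 1.68 and 3.14. Mbd2 and Mbd3 rose by 0.73 and 0.98, Zbtb4 rose by 1.77 and Gadd45b, a stress response gene, rose by 2.13. The list had adjusted p = 0.014 at the preset correlation and adjusted p = 0.406 with an estimated correlation. Of 26 Polycomb genes, 14 fell and 9 rose, with Ezh2, the histone methyltransferase, down by a log2 change of -4.50 (adjusted p = 0.216 for the list, and adjusted p = 0.477 with an estimated correlation).

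The other genes with the largest increases were Oxt, Ntsr2, Gpr37l1, Cplx3, Neu4 and the microRNA entry mmu-mir-2134-4, which stood at 297 and 908 CPM in the dMSN libraries. Neu4 had 0 counts in yMSN and was at least 199.6-fold higher in dMSN. The largest decreases were mostly of genes from tissues outside the brain that were abundant in yMSN. With 0 counts in both dMSN libraries and a floor of 3 counts over the group, Actc1, a muscle actin, was at least 32595-fold lower. On the same terms Ugt2a1, of the olfactory epithelium, was at least 14956-fold lower and Krt13 at least 5209-fold lower. Bpifa1, of the upper airway, stood at 319 CPM in yMSN, Ibsp, a bone matrix protein, at 322 CPM and Krt5 at 125 CPM. Xist, Aox3l1, Krt6a, Atp1b4 and Nrk were also among the 12.

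The tests were made in edgeR with 1 residual degree of freedom, the difference between the dMSN libraries, and the lone yMSN library was assumed to vary like them. With lineage and stage as terms the count of 12948 became 11504, and in that model it was 6609 without dMSN 1 and 7073 without dMSN 2, where 1 mean per cell group leaves no residual degree of freedom.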

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

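The tests on Xist and Y-linked genes, on exchanged labels and on the share of genes going the same way were chosen only after the result was seen. The explanation tested by that share was also narrowed to genes that differ 2-fold, and the limit of 5 CPM was added, after a result was seen.

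Some genes moved in opposite directions in the lineages, and these differences were not tested, since each group has 1 library. The log2 change from SP to yMSN less that from HP to yCA was 17.38 for Ddx3y, 16.36 for Kdm5d, 16.33 for Eif2s3y, 11.08 for Sult1e1 and 9.98 for Acsm4. It was -10.30 for Hoxa2 and -6.71 for Kcne2. Some lists also moved in opposite directions, likewise untested. Of the lists fixed beforehand, they are given where both medians lay outside the 95% range of matched random lists, a criterion chosen after the data had been seen. The median of yMSN minus yCA less that of SP minus HP was -1.30 for immature neuron genes, -0.81 for synapse genes, -1.12 for medium spiny neuron signalling genes, -0.85 for hippocampal neuron genes, 2.43 for meningeal and fibroblast genes and 11.58 for sex-linked genes. For sex-linked genes it was also 11.58 between the lineages' changes. Of the lists written later, midbrain, hindbrain and spinal cord had medians of 2.24 in SP minus HP and -0.30 in yMSN minus yCA. Both lay outside the random range, but this decides nothing, since the list was written for tissue seen or suspected in the libraries. In the young pair its median level was 0.360 CPM in yCA and 0.138 CPM in yMSN, near the counting floors of 0.0771 and 0.0691 CPM. The opposite direction there says little.

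Transcripts of non-brain tissue were present in yCA and yMSN. Low counts spread over genes of every tissue are argued against by genes of liver, lung, kidney and gut. Their median was 0.0514 CPM in yCA and 0.0691 CPM in yMSN, at or below the counting floors of 0.0771 and 0.0691 CPM. It was at most 0.102% of that of the skeletal muscle genes in these libraries. That list was written after some of its members had been seen, so a low ratio was likely from the start. Tissue of the head outside the brain may be in these libraries: 19 genes of skin and mouth lining, none of them looked at before (1 gene already seen was left out), had a median log2 level 3.66 above dMSN in yCA and 5.23 above dMSN in yMSN. Of those 19 genes, 4 are above 5 CPM in dMSN, and the most abundant in yMSN were Krt5 at 125 CPM and Krt15 at 122 CPM. The olfactory epithelium and the bone and cartilage lists had medians of 35.4 and 28.5 CPM in yMSN, against 0.244 and 1.52 CPM in yCA. A change of stage shared by both young libraries would not account for these lists. For the skeletal muscle list and the skin and mouth lining genes, high in both, the young stage stays open as an untested biological explanation, since each young group is 1 library.

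Xist was high in SP and yCA, where the 3 Y-linked genes had 0 counts, although the labels say male. A failure to count Y-linked genes is argued against by 672 counts in HP and 2108 in yMSN. Female tissue under a male label may account for SP and yCA, where Xist in yCA, the lower of them, was 45833 times the dMSN mean, which rests on 4 counts. HP and yMSN held both Xist and Y-linked transcripts, so tissue of both sexes may have been pooled there. No biological explanation was tested, since the labels give a single sex.

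In edgeR with lineage and stage as terms, 0 genes passed for striatal against hippocampal, as with limma voom, while DESeq2 called 60 and 1 mean per cell group in edgeR called 356. Whether a difference is shared across the genes that differ 2-fold cannot be decided here. There were 82 genes 2-fold apart in both pairs with at least 5 CPM in the higher library of each. Of these, 11 (13.4%, exact 95% interval 6.89% to 22.7%) went the same way, and 277 of 682 (40.6%) did with no such limit. Genes are not independent, and the pallial list was lower at both stages. The share also counts differences of sex between libraries, such as Ddx3y at -8.00 in SP minus HP and 9.37 in yMSN minus yCA. An exchange of the HP and SP labels would turn the share round. Exchanged labels of HP and SP cannot be told apart from the given ones, because the pallial less the subpallial median was -0.33 in SP minus HP with a 95% bootstrap interval of -1.16 to 0.67, and members went both ways. Non-brain tissue in the young pair may contribute. Among 10122 genes at 10 CPM or more in both dMSN libraries r was -0.32, which met the bound set beforehand against it, but that bound was wrong: the filter keeps brain genes that other tissue would dilute, and the synapse list, at -0.45 in yMSN minus yCA, was lower there.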

How the results depend on the processing

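The alternatives with thinned dMSN libraries, with yCA in place of yMSN and with genes at 10 CPM in dMSN were added after seeing the data. No paired analysis was possible because the groups compared share only replicate number 1. For young against precursor the count was 4421 without dMSN and 3590 to 7355 with single libraries left out. For striatal against hippocampal it was 60 with DESeq2, 356 with 1 mean per cell group, and 0 to 1515 with single libraries left out (1495 without HP, 1515 without SP, 116 without yCA, 130 without yMSN). Without HP, SP, yCA or yMSN both of these contrasts rest on 1 pair of libraries, with the spread from the dMSN pair. For dMSN against yMSN it was 6609 to 12943 with single libraries left out, and no value can be had without yMSN. The 6609 without dMSN 1 and 7073 without dMSN 2 come from the model with lineage and stage, which gave 11504 with all libraries, and the other values from 1 mean per cell group. Without 1 dMSN library the lone one is assumed to vary like the other groups. The lists past the threshold numbered 0 in each comparison with an estimated correlation, a version that hardly any list could pass with 2 or 1 degrees of freedom. Among genes with a mean of at least 10 CPM, r was 0.850 for the lineages and -0.320 for the stages. The cause of these changes was not tested. Signs reversed for genes that did not pass: with RLE scaling and with DESeq2, Tet1 was -0.054 and Alas2 -0.062. With single libraries left out, Tet1 ranged from -0.29 to 0.34, Tet2 from -0.34 to 0.61, Tet3 from -0.33 to 0.10 and Alas2 from -0.21 to 0.33. Upper quartile scaling moved the median log2 change of dMSN against yMSN from -0.11 to -0.27. With dMSN thinned the counts were 6721, 0 and 10638. With yCA in place of yMSN the count was 12865, of which 11166 were shared and 11048 went the same way. In genes at 10 CPM in dMSN the striatal against hippocampal count was 0. Of the genes named or listed, 74 of 85, 2 of 23 and 79 of 87 kept their direction and side of the threshold under all alternatives run. Depth limits single pairs at low counts, where a count of 0 allows up to 0.0861 CPM in HP.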

Other observations

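Several groups were measured that the comparisons above leave aside. For young against precursor, 12 of 26 Polycomb genes fell and 5 rose (adjusted p = 0.064, and adjusted p = 0.328 with an estimated correlation). Ezh2 fell by 1.42 and Cbx2 fell by 2.10 on the log2 scale. Of 26 imprinted genes 11 rose and 4 fell (adjusted p = 0.497, and adjusted p = 0.762 with an estimated correlation). Of 12 erythroid genes 7 fell and 4 rose (adjusted p = 1.1e-06, and adjusted p = 0.328 with an estimated correlation), and Hbb-b1, a globin made after the embryonic ones, was among those that rose, by 7.61. Of 13 astrocyte genes 8 rose and 1 fell, Aldoc by 5.30 (adjusted p = 6.3e-05, and adjusted p = 0.328 with an estimated correlation).

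Of 18 hippocampal neuron marker genes 9 rose from precursor to young (adjusted p = 0.018, and adjusted p = 0.498 with an estimated correlation). Of 5 germ line genes tested none passed for young against precursor (adjusted p = 0.734, and adjusted p = 0.762 with an estimated correlation). The liver list had a median of 0.0514 CPM in yCA and 0.0806 CPM in yMSN. The heart list had a median of 1.41 CPM in yCA and 3.36 CPM in yMSN, and the thyroid and parathyroid list 1.54 CPM in yCA and 0.691 CPM in yMSN. The lung, kidney and gut list had a median of 0.0514 CPM in yCA and 0.0691 CPM in yMSN.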
